A study of Mus musculus with 14 samples.

How the data were processed

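H3K9ac ChIP-seq libraries of regenerating liver from male C57BL6/J mice aged 2 to 3 months, harvested 12 h after partial hepatectomy, were analysed from the peak tables the authors deposited, 1 per library (6 titled d22 and 6 titled pbs). The 2 pooled input libraries had no tables here and were not analysed. Titles and treatment labels contradict each other (d22 with the vehicle label, pbs with dextrose, and both inputs with dextrose). Libraries were grouped by title, and no condition was inferred from the values.

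Per the submitters' processing notes, bases were called with CASAVA 1.8, reads were aligned with Novoalign to mm10 and peaks were called with MACS 1.4.2. Per the file headers, MACS used a p-value cutoff of 1e-05, an effective genome size of 1.87e+09, a band width of 300 bp, a model fold of 10 to 30, at most 1 tag per position and a regional background of 1000 and 10000 bp. Each library was called alone, against 1 pooled input shared by all libraries of its title group (12526421 tags for d22, 10409931 for pbs). The header gave tags of 48 bp for pbs 1, pbs 4 and pbs 6 and 49 bp for the others. Per the file headers, the deposited columns used were the count of tags in each peak (raw, unscaled), a score of -10 times the log10 of the p-value, a fold enrichment ratio over the local background, and a false discovery rate in percent. Each is the authors' own value for that peak, and fold enrichments and false discovery rates were compared between libraries only as medians per library and, for fold enrichment, as a named alternative. The bed files repeat the peaks and were not used.

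Overlapping peaks of all 12 lists were merged into 57979 consensus regions, of which 12375 had a peak in all 12 libraries (median width 2752 bp) and 27269 in 1 library. A library's tags in a region are the sum over its peaks there. A region missing from a list has no count, not a count of 0, so tag counts were tested only where all 12 had a peak. Counts were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood test with robust estimation, TMM normalization, group as the only term) and Benjamini-Hochberg adjustment at 0.05. CPM values were scaled by edgeR to the tags in the tested regions, not to all tags of the library. Standard errors are the size of the log2 fold change divided by the root of the F statistic.

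Gene names came from a RefSeq gene table of GRCm38.p6, whose coordinates are those of mm10 (49997 genes, 21900 protein-coding). It gives the lower and upper end of each gene but neither strand nor exons nor transcription start sites. The planned window around start sites was therefore replaced by 1 kb on each side of either end of a protein-coding gene, so some regions named for a gene lie at its 3' end. A gene took the region with the most tags among those at its ends, which gave 10329 genes at 8594 regions. The designs, alternatives, gene lists and the rule for named genes were set in advance. The rule took genes with an adjusted p under 0.05 and 1 sign on leaving out each library, and named the 15 largest changes in each direction, with genes sharing a region named together, the 3 members of each list with the smallest p, and for occupancy the 5 regions with the smallest p in each direction. For occupancy the text departs from this rule and names all regions called in every library of 1 group and in 0 of the other. Predicted genes were counted but not named where others were left.

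There were 31 gene lists: cell cycle (early and late), p53 targets and inhibitors, immediate early genes, gluconeogenesis, glycolysis with ChREBP targets, fat synthesis, cholesterol synthesis, fatty acid oxidation, adipogenic genes, bile acids, urea cycle and amino acids, xenobiotic P450, acute phase, secreted hepatocyte proteins, endoplasmic reticulum stress, insulin and nutrients, clock, histone acetylation enzymes, autophagy, interferon, ribosomal proteins, ribosome biogenesis, Wnt and pericentral genes, and 7 cell types (macrophage, neutrophil, lymphocyte, endothelial, stellate, cholangiocyte, erythroid). The 25 lists with at least 5 regions were tested with camera (limma 3.58.1, preset correlation 0.01, prior count 2), beside an estimated correlation and fry. Some genes are in more than 1 list. Values of 1 list member are not reported here.

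Measures of 1 value per library were compared by exact permutation tests (SciPy 1.17.1), peak sets by the Jaccard index of base pairs (bedtools 2.31.1) and occupancy by Fisher's exact test in regions called in 2 to 10 libraries. No pair of libraries was a duplicate: the chi-square per degree of freedom of their counts was 2.41 to 10.3 over 66 pairs. Depth ran from 6343891 to 13259411 tags, and a region's counts carry counting error that the tests include.

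The tests were tried on simulated data with the means, spread and library sizes of these libraries. For d22 minus pbs with 12375 regions, edgeR recovered 50% of 100 regions changed 1.5-fold and 79% of 100 changed 2-fold, with 7 false calls among 136 (5.15%), and made 0 calls without change. DESeq2 recovered 59% and 86%, with 25 false among 170 (14.7%). A list of 16 regions changed 1.2-fold was found by camera with either correlation and by fry, with 0 other lists passing (8594 regions). The simulated regions varied independently of each other, whereas the estimated correlation within the real lists reached 0.38. This simulation therefore does not show how often camera with the preset correlation calls a list wrongly here. For occupancy, 200 fully exclusive regions among 17000 were not found and 2000 were, with 2009 regions passing.

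The alternatives were library totals, DESeq2 1.42.0, tags per kb of peak and fold enrichment (limma), a mean of at least 50 tags, a peak in at least 3 libraries of each group, peaks within 500 bp merged, exactly 1 peak per library, a score of at least 100, peaks covering at least 50% of a region, a window of 2 kb, the title number as a block, and each library left out. Added after the data were seen were both shallowest libraries left out, regions of the 11 libraries other than d22 4, and only the 9 libraries with 49 bp tags (6 d22, 3 pbs). Also chosen then was a comparison of the 125 regions that passed with the 125 of smallest p in each of 99 other splits of the libraries, for tags per kb and for the sign of neighbours.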

Results

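Histone H3 lysine 9 acetylation (H3K9ac), a mark of active promoters and enhancers, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in regenerating mouse liver 12 h after partial hepatectomy. The study asked how delaying the fall in blood glucose that follows the operation affects this mark. There were 12 libraries, 6 titled d22 and 6 titled pbs, each with its own list of peaks on mm10. The titles and the treatment labels contradict each other: libraries titled d22 carry the vehicle label, and those titled pbs carry the label of 22.5% dextrose. Libraries are therefore named by title, every difference is d22 minus pbs, and no library is said here to come from a dextrose-treated or a vehicle-treated mouse. Per the file headers, 6343891 (d22 4) to 13259411 (pbs 1) tags remained per library after filtering. Nothing in the labels says that the libraries came from separate animals, so p-values measure only the spread between these samples, which may be partly technical.

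The acetylated part of the genome was of similar size in the title groups. Peaks numbered 30760 ± 6939 (SD, n = 6) in d22 and 28901 ± 1743 (SD, n = 6) in pbs (two-sided exact permutation test, p = 0.803). They covered 35.9 ± 5.12 Mb and 37.1 ± 5.96 Mb (SD, n = 6 each, exact permutation p = 0.699). The share of peaks at the ends of protein-coding genes, either end ± 1 kb, was 42.8 ± 7.00% in d22 and 44.6 ± 1.51% in pbs (SD, n = 6 each, exact permutation p = 0.755). Peaks held 20.1 ± 3.13% of the tags in d22 and 22.9 ± 2.43% in pbs (SD, n = 6 each, exact permutation p = 0.115). Library d22 4 listed 44585 peaks against 26352 to 30780 in the other 11, and without it the difference in peak number changed from 1859 to -906 and that in the gene-end share from -1.76 to 0.912 percentage points. The difference in covered length, -1.21 Mb, turned to 0.0359 Mb without d22 5, 0.0640 Mb without pbs 1 and 0.307 Mb without pbs 6.

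Peak sets overlapped about as much between the groups as within them, with a mean Jaccard index of 0.605 within and 0.599 between groups (1-sided exact permutation over all splits into 6 and 6, p = 0.132). Without pbs 1, pbs 2, pbs 4, pbs 5 or pbs 6 that small difference changed sign, down to -0.00171. The authors' fold enrichment over pooled input differed: its median per library was 14.1 ± 1.02 in d22 and 16.9 ± 1.29 in pbs (SD, n = 6 each, exact permutation p = 0.00216, the smallest p that 6 against 6 allows). The median false discovery rate that the caller gave was 9.97 ± 2.64% in d22 and 22.3 ± 6.45% in pbs (SD, n = 6 each, exact permutation p = 0.00433). All 6 d22 libraries were called against 1 pooled input and all 6 pbs libraries against the other, so the input and the group cannot be told apart in these 2 measures. Which peaks were listed, and how wide, may also depend on the input. The same limit therefore applies to peak number, covered length, tags summed over the peaks of a region, and occupancy.

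**Figure D1:**
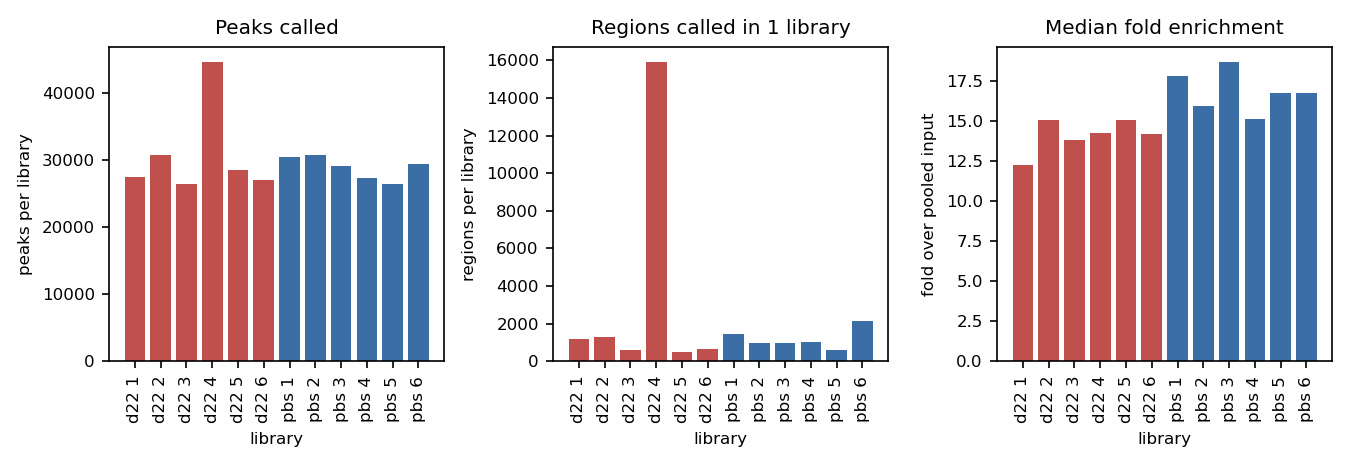
Peaks called, regions called in that library alone and median fold enrichment over pooled input, 1 bar per library (red, d22; blue, pbs). Library d22 4 had 44585 peaks and 15916 regions of its own, against 494 to 2141 regions in the others.

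Gains of H3K9ac tags in d22 at gene ends included some at genes of sugar and fat metabolism, and all these regions were also called wider in d22. The region at Thrsp, a gene of hepatic fat synthesis (chromosome 7, 97414066 to 97421845), had 202 ± 37.9 CPM (tags scaled to all tags in the tested regions) in d22 and 80.4 ± 21.5 in pbs (SD, n = 6 each; log2 fold change 1.30 ± 0.16 SE, edgeR adjusted p = 0.000443). Pklr, which encodes liver pyruvate kinase (chromosome 3, 89135893 to 89140996), had 119 ± 44.3 and 48.6 ± 9.60 CPM (SD, n = 6 each; log2 fold change 1.25 ± 0.20 SE, edgeR adjusted p = 0.00599). Gpi1 (glucose-6-phosphate isomerase) rose by 0.81 on the log2 scale, the region shared by Khk (ketohexokinase, the entry of fructose into metabolism) and Emilin1 by 0.50, and Aacs (acetoacetyl-CoA synthetase) by 0.59. The changes of the other named regions were 1.37 at Cyp2c70, a P450 of muricholic acid synthesis (chromosome 19, 40183352 to 40188092), 1.33 at Rgs16, a regulator of G protein signalling, 1.09 at the region shared by Aff4 and Leap2, a liver-secreted ghrelin receptor antagonist, and 0.61 at the manganese exporter Slc30a10. H3K9ac was also higher at Chac1 (glutathione breakdown) by 1.06, Usp10 (a deubiquitinase) by 0.54, Tars (threonyl-tRNA synthetase) by 0.54, Ube2g2 (a ubiquitin-conjugating enzyme) by 0.53 and the region shared by Derl2 (endoplasmic reticulum-associated degradation) and Mis12 by 0.49. The change at Tcim was 0.56. With library totals as the only scaling, Aacs, Slc30a10, Usp10, Tars, Ube2g2, Tcim and the regions of Khk and Derl2 lost their call (edgeR adjusted p = 0.134 to 0.241).

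Losses of H3K9ac tags in d22 at gene ends included those at Gstt2, Fads2 and Acot2, and all these regions were also called narrower in d22. The region at Gstt2, a glutathione transferase (chromosome 10, 75831982 to 75838317), had 107 ± 19.3 CPM in d22 and 198 ± 10.6 in pbs (SD, n = 6 each; log2 fold change -0.87 ± 0.10 SE, edgeR adjusted p = 0.000443). Fads2, the delta-6 desaturase of polyunsaturated fatty acids (chromosome 19, 10096549 to 10102986), had 104 ± 11.2 and 182 ± 19.9 CPM (SD, n = 6 each; log2 fold change -0.80 ± 0.09 SE, edgeR adjusted p = 0.000443). Further lipid genes fell by 1.14 (Acaa1b, peroxisomal thiolase), 0.98 (Acot2, a mitochondrial acyl-CoA thioesterase), 0.99 (Pctp, phosphatidylcholine transfer protein) and 0.76 on the log2 scale (Aldh3a2, fatty aldehyde dehydrogenase). Agxt, which detoxifies glyoxylate, fell by 1.03, Slc25a13, the mitochondrial aspartate-glutamate carrier, fell by 0.82, and the transporters Abcc3 and Slc22a18 changed by -0.84 and -0.88. The region shared by Fcamr and Pigr, the receptor that carries polymeric antibodies into bile, fell by 1.17, that at the corepressor Cbfa2t3 fell by 1.13, that at Depp1, a FoxO target, fell by 0.90, that at Igfbp2 fell by 0.86 and that shared by Lrrc61 and Rarres2 (chemerin) fell by 0.73.

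These regions were the 15 in each direction that the rule for named genes gave, which takes 1 region per gene, that with the most tags, and leaves out predicted genes. Over all places 125 regions passed (56 higher and 69 lower in d22), of 12375 regions with a peak in all 12 libraries (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05, 1348 at unadjusted p under 0.05). The median size of the change was 0.74 for the higher and 0.69 for the lower regions on the log2 scale. All 125 kept their sign on leaving out each library in turn, and 51 also kept their call; of the 30 named regions 20 kept it. Chac1 lost it without pbs 4 (edgeR adjusted p = 0.0551) and Usp10 without pbs 3 or pbs 4 (highest edgeR adjusted p = 0.0521). Abcc3 lost it without d22 2, d22 6, pbs 3 or pbs 5 (highest 0.0608), Agxt without d22 1, pbs 4, pbs 5 or pbs 6 (0.0782) and Acaa1b without d22 2, d22 6, pbs 3, pbs 5 or pbs 6 (0.0658). Tars lost it without d22 5, d22 6 or any pbs library except pbs 3 and pbs 4 (0.0755), Pctp without d22 2, d22 4, d22 5, d22 6, pbs 2, pbs 3 or pbs 4 (0.0710), and the Derl2 and Mis12 region without d22 1, d22 2, d22 6 or any pbs library except pbs 2 (0.0914). Slc22a18 kept its call only without pbs 2 or pbs 6 (0.114) and Tcim only without pbs 3 (0.104). The number passing was 72 without d22 2, 70 without d22 6, 76 without pbs 2, 64 without pbs 3, 69 without pbs 4 and 70 without pbs 5.

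The tag count of a region also depends on how widely it was called. In all 125 regions that passed, the called length moved the same way as the tag count (median sizes of 0.52 and 0.72, log2). At Pklr the mean called length was 3333 bp in d22 and 1537 bp in pbs. Its tags per kb of called peak changed by only 0.04 relative to all regions. Scaled to tags per kb of called peak, 5 regions passed (4 higher, 1 lower, limma), among them Aff4 and Leap2 (0.75), a region inside Aacs (0.85) and another 22230 bp from Ppp1r3b (0.84). On that scale Ube2g2 (-0.09), Slc25a13 (0.09), Fads2 (0.01) and Aldh3a2 (0.13) had the opposite sign. Relative to the median of all regions in tags per kb, which was 0.09, the sign was opposite for Ube2g2 (-0.18), Aldh3a2 (0.05), Aacs (-0.05) and Gpi1 (-0.01). Of regions with exactly 1 peak in every library, 0 of 2599 passed by edgeR (184 at unadjusted p under 0.05), with only 2 of the 125 among them. Library totals as the only scaling shifted all regions by a median of -0.22 and gave 454 regions (26 higher, 428 lower), and the authors' fold enrichment shifted them by -0.30 and gave 2503 (166 higher, 2337 lower). Relative to that shift in fold enrichment, Gpi1 (-0.01), Aacs (-0.32), Usp10 (-0.48) and Slc25a13 (0.47) changed sign.

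**Figure D2:**
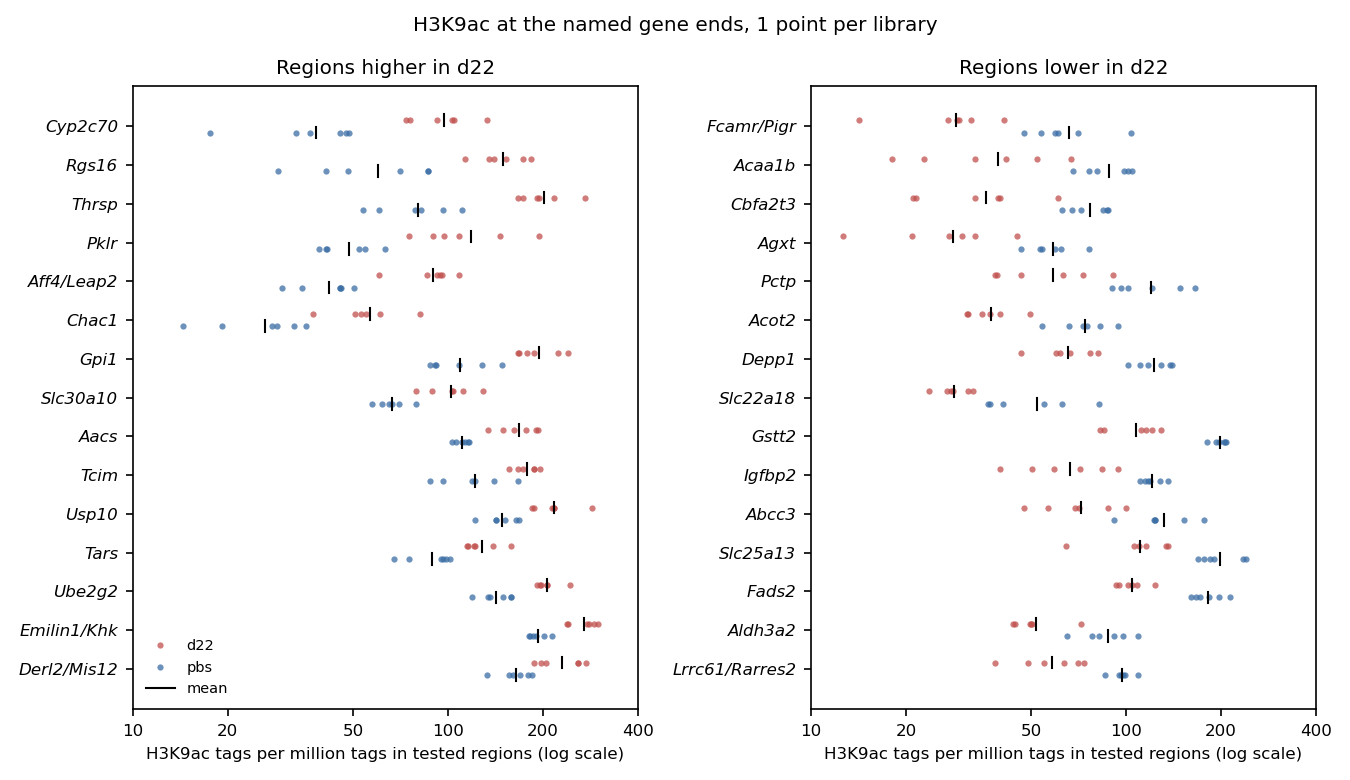
H3K9ac CPM (log axis) at the 30 named regions, 1 point per library (red, d22; blue, pbs) with the group mean as a black line. At Thrsp the means were 202 and 80.4, and at Gstt2 they were 107 and 198.

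Among gene lists fixed before the data were examined, those of fatty acid oxidation and cholesterol synthesis had the smallest camera p for a loss of H3K9ac in d22 with the preset correlation. By fry, cholesterol synthesis (adjusted p = 0.121) also came after the clock (0.0617), urea cycle (0.0775), secreted hepatocyte (0.0775) and first cell cycle (0.108) lists. Of 16 regions at fatty acid oxidation genes, controlled in liver by PPAR-alpha, 15 had a negative value and 1 passed over all regions (Acot2), with 6 lower when adjusted over the list alone: Acot2, Acadl (-0.44), Angptl4 (-0.32), Ppara (-0.32), Cpt1a (-0.30) and Slc25a20 (-0.28). The list's median was -0.24 (camera adjusted p = 5.92e-07; adjusted p = 0.163 with an estimated correlation). All 20 cholesterol synthesis regions had negative values, 0 passed over all regions by edgeR and 1 (Srebf2, the regulator of the pathway, -0.34) when adjusted over the list alone. Their median was -0.21 (camera adjusted p = 2.73e-05; adjusted p = 0.346 with an estimated correlation). The urea cycle and amino acid list (17 regions, median -0.13) also passed with a preset correlation (camera adjusted p = 0.00558; adjusted p = 0.346 with an estimated correlation). Over all regions 0 of its members passed by edgeR, and adjusted over the list alone 3 were lower (Nags -0.44, Ass1 -0.45 and Gpt -0.38, whose region is shared with 3 other genes) and 1 was higher (Glul, 0.25).

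Losses were also called for 3 further lists, with 0 members passing over all regions by edgeR in any of them. These were the xenobiotic P450 list (12 regions, median -0.18, camera adjusted p = 0.0334; adjusted p = 0.501 with an estimated correlation), the ribosomal proteins (23 regions, median -0.10, and -0.028 without d22 4, camera adjusted p = 0.0376; adjusted p = 0.521 with an estimated correlation) and the secreted hepatocyte proteins (22 regions, median -0.08, camera adjusted p = 0.0436; adjusted p = 0.346 with an estimated correlation). Adjusted over the list alone, 1 region passed, at Rbp4, the plasma carrier of retinol (-0.43), and 0 in the P450 and ribosomal lists. Values were -0.78 for Cyp3a11, -0.47 for Ugt1a1 and -0.56 for Alb, and 4 of 12 P450, 5 of 23 ribosomal and 8 of 22 secreted regions had positive values. Leaving out single libraries ended these calls: d22 4 or pbs 2 to pbs 5 for the P450 list (highest camera adjusted p = 0.135), d22 1, d22 4, d22 5 or pbs 2 to pbs 4 for the ribosomal list (0.181), and d22 1, d22 2 or pbs 1 to pbs 5 for the secreted list (0.152). In tags per kb, the medians of the urea cycle (0.06), secreted (0.05), ribosomal (0.04) and P450 (0.01) lists were positive, and below the median of all regions. Relative to that median, fatty acid oxidation was at -0.11, cholesterol synthesis at -0.12, endoplasmic reticulum stress at 0.089 and fat synthesis at 0.0052.

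The lists called higher in d22 were those of endoplasmic reticulum stress with ATF4 targets and of SREBP-1c-driven fat synthesis. In the stress list (17 regions, median 0.15), Chac1 (1.06) and Ddit4, an inhibitor of mTORC1 (0.41), rose over all regions and also when adjusted over the list alone (camera adjusted p = 0.0109; adjusted p = 0.346 with an estimated correlation). Ddit4 is also in the insulin and nutrient list, and it lost its call without any of 8 libraries (d22 2, d22 3, d22 5, d22 6 or pbs 2 to pbs 5; highest edgeR adjusted p = 0.114). In the fat synthesis list (14 regions, median 0.13), Thrsp alone rose over all regions, and adjusted over the list alone 3 were higher (Thrsp, Me1 0.60 and Acly 0.30) and Gpam, which starts glycerolipid synthesis, was lower (-0.60; camera adjusted p = 0.0436; adjusted p = 0.346 with an estimated correlation). With library totals as the only scaling these medians were -0.07 and -0.09, and in fold enrichment -0.18 and -0.28, against medians of -0.22 and -0.30 over all regions. The stress call was lost without pbs 6 (camera adjusted p = 0.0575), and the fat synthesis call without any of 6 libraries (d22 1, d22 5, d22 6, pbs 2, pbs 3 or pbs 4; highest camera adjusted p = 0.185).

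Glycolysis genes with targets of the glucose-sensing factor ChREBP went in both directions. Khk, Pklr and Gpi1 rose over all regions, and adjusted over the list alone 5 of 19 regions were higher and 4 lower. Mlxipl, the gene of ChREBP itself, had a value of 1.13 (edgeR adjusted p = 0.0948), while Pgk1 (-0.76), Txnip (-0.34) and Tpi1 (-0.31) had negative values. The list did not pass (camera adjusted p = 0.659), its median (-0.05, and 0.011 without d22 4) was below 0 and its mean (0.08) above, and fry's mixed test, which asks for change in either direction, gave an adjusted p of 3.18e-05. In gluconeogenesis, Pck1, the rate-limiting enzyme, fell by 0.43 (327 CPM in d22 and 439 in pbs), 2 regions were lower when adjusted over the list alone, and the list of 14 did not pass (camera adjusted p = 0.400; fry mixed 0.0069). In the acute phase list, Lcn2 (lipocalin 2) rose by 0.47 and Saa1 had a value of 1.09 (edgeR adjusted p = 0.0546); adjusted over the list alone 2 were higher and 1 (Fga, -0.41) lower, and the list did not pass (camera adjusted p = 0.400; fry mixed 0.00313). In bile acid metabolism Abcc3 fell, with 2 higher and 2 lower when adjusted over the list alone (camera adjusted p = 0.420; fry mixed 0.00313).

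Lists of cell division and growth control did not pass as a whole in either direction. The list of the first cell cycle steps had a camera adjusted p of 0.146 and 0 members passing by edgeR over all regions, with Cdt1 (-0.42) lower when adjusted over the list alone and Ccnd1, the cyclin of cell cycle entry, at -0.41. The later cell cycle list (adjusted p = 0.886), p53 targets and inhibitors (0.952), immediate early genes (0.926), ribosome biogenesis (0.886), interferon response (0.926), autophagy and lysosome (0.926), histone acetylation enzymes (0.659), Wnt and pericentral genes (0.659), adipogenic genes (0.230), insulin and nutrient genes (0.295) and clock genes (0.400) did not pass by camera either. At the 1 region taken for each gene, Ddit4 was the only member of these to pass over all regions. Adjusted over the list alone, members passed in 3 of them: Ddit4, Ulk1 (autophagy start, 0.40), and Tef (0.70), Per3 (-0.51) and Nr1d1 (-0.51) of the clock. Cdkn1a, of the p53 and inhibitor list, had a further region inside the gene, outside these list tests, that passed over all regions (0.75, edgeR adjusted p = 0.0353). That call was lost without some single libraries. Fry's mixed test, for change in either direction, passed for the first cell cycle steps (adjusted p = 0.00434), p53 targets and inhibitors (0.00313) and clock genes (0.00186). Median and camera direction differed in sign for the later cell cycle, autophagy, interferon and ribosome biogenesis lists, all close to 0.

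Marker genes of other liver cell types were sparse among regions with a peak in all 12 libraries. The endothelial list had 9 regions with a median of 0.14 (0 passing by edgeR, camera adjusted p = 0.215), and 0.01 without d22 4. The other lists were too short to test: macrophage 3 regions (median 0.09), cholangiocyte 4 (-0.00, and 0.028 without d22 4), erythroid 3 (-0.16), lymphocyte 2 (0.14, and -0.042 without d22 4), stellate 2 (0.14) and neutrophil 0. Over all 25 lists tested, 8 passed with the preset correlation, 0 with an estimated correlation and 1 by fry (fatty acid oxidation, adjusted p = 0.0248). With the preset correlation 5 passed without d22 1, and 4 without pbs 2, pbs 3 or pbs 4. The fatty acid oxidation, cholesterol and urea cycle lists passed without each library in turn.

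**Figure D3:**
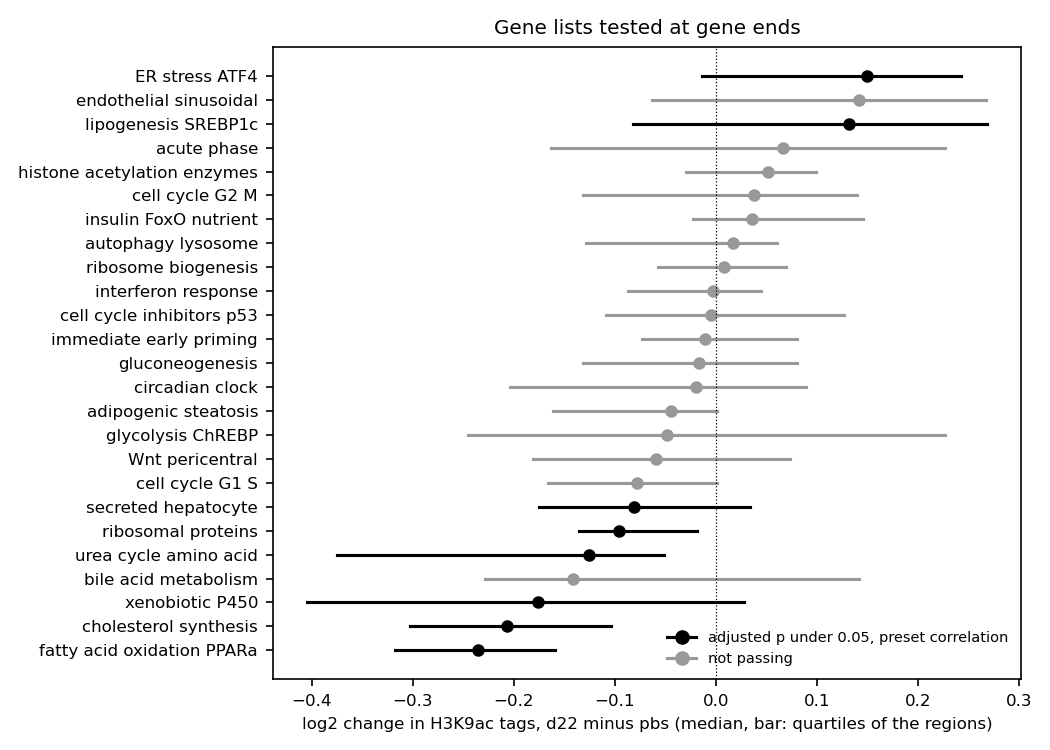
Median log2 change in H3K9ac tags (d22 minus pbs) of the 25 gene lists tested, with bars from the lower to the upper quartile of their regions. Black lists passed with a preset correlation, from -0.24 for fatty acid oxidation to 0.15 for endoplasmic reticulum stress; the last and the fat synthesis list turn negative with library totals or fold enrichment, but stay above the median of all regions.

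Some weaker regions were called in nearly all libraries of 1 group and nearly none of the other. Regions called in all 6 d22 libraries and in 0 pbs libraries were found at Ggt6, inside Exoc3l2 and 8993 bp from Stoml1. Regions called in all 6 pbs libraries and in 0 d22 libraries numbered 9, inside Rnf19a, Zc3h13, Det1, Il1rn (the interleukin-1 receptor antagonist), Gramd3 and Unc93a and nearest to Gm7697, Opn4 and Akr1c6. They held means of 16.2 to 30.8 tags per library. With at least 5 libraries of 1 group and at most 1 of the other, 259 regions qualified, 95 on the d22 side and 164 on the pbs side.

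None of these differences in occupancy passed a test: 0 of 16871 regions did (Fisher's exact test per region, Benjamini-Hochberg adjusted, 99 at unadjusted p under 0.05). The smallest p that 6 against 6 allows is 0.00216 (exact), and 731 regions at that value would have been needed for any to pass. Such a region is one that the caller did not list, which does not show that the mark was absent there at this depth.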

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

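Chosen after the results were seen were the tests of chance for the regions with different tag counts, of the share of hepatocytes, of chance for regions called almost only in 1 group, of low depth and of the pooled input, and the comparison of tags per kb with the other splits. Chance alone sets about 1 in 20 groups apart by the rule used here, Dixon's test of the extreme library in each group of 6. Among 24 groups of library measures 5 stood out (1.2 by chance), and among 60 groups of CPM values at the named regions 3 did (3 by chance).

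Chance is argued against for the number of regions that passed, though not for any single region: 1 of 100 splits of the libraries, the real one, gave as many as 125, and the highest other split gave 3. At unadjusted p under 0.05, where the real split gave 1348, 2 of the 100 gave as many, the real one included, and the highest other (d22 1, d22 4, d22 5, d22 6, pbs 1 and pbs 6 against the rest) gave 1363. A change in the width of the called peaks alone stays open: tags per kb moved with the tag counts (lower quartile 0.116, median 0.24, log2, relative to all regions), but among the 125 regions of smallest p in 99 other splits the lower quartile was as large in 3, the median in 0, and the median as a share of the change in tag counts (0.330) in 35, so choosing on tag counts gives such a share by itself. A lower share of hepatocytes in d22 stays open. The secreted hepatocyte genes had a median of -0.081 (quartiles -0.17 to 0.03), while the smallest of the 69 lower regions was at -0.36. Those regions were chosen for passing, which leaves out small changes, so this comparison cannot decide. The secreted list was called lower and Alb had -0.56. Medians were positive for the endothelial (0.14, and 0.01 without d22 4), stellate (0.14), lymphocyte (0.14, and -0.042 without d22 4) and macrophage (0.09) lists. They were -0.004 for the cholangiocyte and -0.16 for the erythroid list. A biological effect of the treatment stays open and untested as such, since the titles and treatment labels conflict and the pooled input differed between the groups.

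Library d22 4 stood apart from the other d22 libraries, with 44585 peaks (26352 to 30698 in the others), 15916 regions called in no other library (494 to 1286), 29.5% of its peaks at gene ends (42.2 to 48.5%) and a mean Jaccard index of 0.430 with the other libraries (0.611 to 0.634). Low sequencing depth did not give as many such regions in pbs 3, which had a similar depth (6385610 against 6343891 tags) and 947 of them. That library was called against the other pooled input, so low depth against the input used for d22 was not tested and stays open. Scattered background tags called as peaks cannot be told apart from weak acetylation: these regions lay at gene ends 0.658 times as often as the same intervals shifted along the chromosome, but regions private to 1 library cannot lie where the libraries share peaks, many of them gene ends. No biological explanation was tested.

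The lower median fold enrichment in d22 (12.3 to 15.1 per library, against 15.1 to 18.7 in pbs) cannot be told apart from a different pooled input for each title group, because 0 libraries were called against the other group's input. A difference in immunoprecipitation yield or in acetylation itself stays open as well.

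In pbs 3, peaks on unplaced sequences held 674 tags for each 1e+06 sequenced, against 28.7 to 53.7 in the other pbs libraries. At Usp10 the highest d22 value was 286 CPM in d22 4, with 185 to 218 in the other d22 libraries. Ube2g2 reached 243 CPM in d22 2 (192 to 206 in the others), and Aldh3a2 reached 71.7 CPM in d22 6 (43.6 to 50.3 in the others).

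Chance is unlikely but not excluded for the number of gene lists that passed with the preset correlation. The real split gave 8, 1 of 100 splits gave as many, the real one included, and the highest other split gave 7. Only some of the possible splits were drawn, so another could reach 8. The real split itself gave 0 lists with an estimated correlation and 1 by fry. With the preset correlation it gave 4 without pbs 2, pbs 3 or pbs 4. For the regions called in at least 5 libraries of 1 group and at most 1 of the other, 7 of all splits into 6 and 6, the real one included, gave as many as the real 259. That share is under 0.05, so chance is unlikely but not excluded by this test, which was chosen after the results were seen. The highest other split gave 321, with d22 1, d22 2, pbs 1, pbs 2, pbs 5 and pbs 6 on the same side. Those 6 libraries had more covered length (means of 39.5 and 33.4 Mb), so how much was called also sorts the libraries.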

How the results depend on the processing

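Leaving out both shallowest libraries, regions of the 11 libraries other than d22 4, and libraries with 49 bp tags only were tests chosen after the data were seen. The share of tags in peaks, the median fold enrichment and the median false discovery rate kept their side of the threshold and their direction in all of their 16, 2 and 2 alternatives. The occupancy test gave 0 passing in all 18, which says nothing about stability, since it could hardly pass in any. The number of regions with different tag counts stayed within 1.5 times of 125 in 13 of 25, and the number of gene lists within 1.5 times of 8 in 11 of 20.

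Among measures that did not differ, the difference in peak number was -268 with stricter peaks and -869 without both shallowest libraries, where the gene-end share differed by 1.14 percentage points. With 49 bp tags only, covered length differed by 2.77 Mb and the Jaccard indices by -0.0159. Leaving out 1 library gave -906 to 2741 peaks, -2.76 to 0.307 Mb, -2.89 to 0.912 percentage points and Jaccard differences of -0.00171 to 0.0160. The cause was not tested.

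Different tag counts were found in 454 regions with library totals, 272 with DESeq2 (all 125 among them), 5 by tag density, 2503 by fold enrichment, 0 with exactly 1 peak in every library and 39 with 49 bp tags only, where 3 pbs libraries were left. Leaving out 1 library gave 64 to 139. Tests of fewer libraries or regions have less power. The shifts of -0.22 and -0.30 over all regions may raise the numbers with library totals and fold enrichment, but how far was not tested. For the others the cause was not tested. Of the 30 named regions, 30 kept their call with DESeq2, 22 with library totals, 15 by fold enrichment, 11 with 49 bp tags only and 1 by tag density. The 8 that lost it with library totals were all gains in d22, and every named loss kept it.

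Regions called almost only in 1 group numbered 129 with stricter peaks, 599 without both shallowest libraries, 1505 with 49 bp tags only and 362 to 454 without 1 library. With fewer libraries the rule asks for fewer, which raises these numbers by construction.

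Gene lists passing numbered 0 with an estimated correlation, 1 with fry, 2 by tag density, 0 by fold enrichment, 4 without both shallowest libraries, and 4 to 8 without 1 library. By fold enrichment the camera direction of the urea cycle and ribosomal lists changed (camera adjusted p = 0.993 for both). Their medians stayed below that of all regions, at -0.023 and -0.032 relative to it. With library totals the medians of the fat synthesis and endoplasmic reticulum stress lists were -0.091 and -0.070, above the shift of all regions. Relative to all regions, fold enrichment reversed Gpi1 (-0.011), Aacs (-0.32), Usp10 (-0.48) and Slc25a13 (0.47), while tag density as measured reversed Ube2g2 (-0.091), Slc25a13 (0.085), Fads2 (0.014) and Aldh3a2 (0.13), of which Slc25a13 and Fads2 were not reversed relative to all regions. The cause was not tested.

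With the title number as a block, 128 regions (97 of the 125) and 6 lists passed, and peak numbers gave p = 0.938 (exact permutation within numbers). After the mean of each group was subtracted in every region, the deviations of libraries of 1 number had correlations of -0.01 to 0.16. The number may therefore be no more than a name. Only 12375 of 57979 regions had a peak in every library and were testable for tag counts; how far depth limits this was not tested.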

Other observations

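The features in this part were chosen after their values were seen; the tests of place and of neighbours were written down before they were run, except the comparison of neighbours with other splits, which was chosen after. Some regions that passed lay away from gene ends. H3K9ac was higher in d22 22230 bp from Ppp1r3b, the liver glycogen-targeting subunit of protein phosphatase 1 (1.56, edgeR adjusted p = 0.00336), 2217 bp from Pygl, liver glycogen phosphorylase (1.33), and inside Serpina12, which encodes vaspin (1.42), Csad, of taurine synthesis (0.98), and Cdkn1a, the cell cycle inhibitor p21 (0.75). It was lower inside Abcc2, a canalicular transporter (-1.43), 5835 bp from Ahcy, adenosylhomocysteinase (27.7 against 64.7 CPM), and 36667 bp from Insig1, which restrains cholesterol synthesis (-0.77). Cdkn1a lost its call without d22 1 or pbs 2 to pbs 6 (highest edgeR adjusted p = 0.0811) and Insig1 without d22 2, d22 3, d22 6 or pbs 2 to pbs 5 (0.0825). The others in this paragraph kept it without each library in turn.

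Some genes held several regions that moved together. Aacs had 3 regions higher in d22 (0.59 to 1.92), 1 of them at the gene end, and Gpam had 2 lower regions inside the gene (-1.24 and -0.84) besides the region at its end (-0.60). At Cbfa2t3 (-1.13 and -0.51) and Zfp395 (-0.93 and -0.52) 2 regions each were lower. Lpin1, of the fat synthesis list, had 2 higher regions inside the gene, away from its ends (0.64 and 0.68). Crot had a lower region at its end (-0.47) and another 41301 bp away (-0.93). The Lpin1 region of 0.64 kept its call without each library, whereas that of 0.68 and both at Crot did not (highest edgeR adjusted p = 0.113, 0.117 and 0.0851). Without single libraries, calls were lost at the Aacs region of 1.92 (d22 2, d22 4, d22 6, pbs 2, pbs 4, pbs 5 or pbs 6; highest edgeR adjusted p = 0.0646), the Cbfa2t3 region of -0.51 (9 libraries, 0.104) and the Zfp395 region of -0.52 (d22 2, d22 3, d22 6, pbs 4 or pbs 5; 0.0730).

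Regions higher in d22 lay at gene ends less often than lower regions: 22 of 56 (39.3%) against 47 of 69 (68.1%; Fisher's exact p = 0.00199), with 72.6% of all regions there. A difference in width or tag number between regions at and away from gene ends is argued against: the difference was -28.8 percentage points, outside the 95% range of 10000 matched draws (-16.4 to 13.0). Gains in d22 may therefore lie more often at distal elements, a hypothesis that the missing strand and start sites leave open. The comparison was not repeated without d22 4, which had 29.5% of its peaks at gene ends (42.2 to 48.5% in the other d22 libraries).

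Neighbours of regions that passed, at Aacs for example, tended to move the same way. Of 95 such regions with another tested region within 50 kb, the nearest had the same sign in 75 (78.9%), against 54.7% of 8693 other regions. The other regions mostly have values near 0, whose signs carry more noise. In 99 other splits of the libraries, the 125 regions with the smallest p gave shares of up to 80.8% (median 65.6%), and 4 of these were as large. A sign shared by neighbours over the whole genome therefore stays open.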
